A study of Mus musculus with 24 samples.

How the data were processed

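RNA was sequenced from intrahepatic cholangiocytes, the epithelial cells lining the bile ducts inside the liver, of wild-type (WT) mice and of dnTGFB mice, which carry a dominant-negative TGF-β type II receptor and serve as a model of primary biliary cholangitis. Per the labels' protocols, cholangiocytes were captured with an antibody and magnetic beads, and poly(A) RNA was sequenced from 500 ng of total RNA per library. Cells of 6 to 8 mice were pooled for each group, and the RNA of each pool was sequenced in triplicate, so the design holds 1 pool of mice per group. All p-values therefore measure only the spread between libraries of a pool and say nothing about the spread between mice. By the design this spread is technical, but the chi-square per gene to the nearest library of the same group was 40 for male WT library 1, 78.42 for male dnTGFB library 3, 62.68 for female WT secretin library 1, 47.46 for female dnTGFB library 3, 28.82 for female dnTGFB secretin library 1 and 10.55 for female WT library 2, so in these groups it also holds differences of content.

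The authors deposited 1 table per library with a whole-number read count for each of 49315 Ensembl mouse genes, and the values were whole numbers in all 24 tables. The aligner, the counting tool and its strand setting are not given in the sources used here. The genome build was worked out from the coordinates in the tables: 49056 of the gene identifiers are in GENCODE release M21, 49013 of these overlap the M21 gene on the same chromosome, and 44823 have the same chromosome, start and end, so that the coordinates are those of GRCm38. Gene symbols and biotypes were taken from that annotation. Identifiers absent from it took at most 0.02% of a library's counts, and 73 symbols belong to more than 1 identifier. Because strand use is not stated, reads of overlapping antisense genes cannot be told apart.

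Each library's group was taken from its title. The genotype label disagreed with the title in 12 of the 24 libraries: the WT secretin libraries were labelled with the transgene and the untreated dnTGFB libraries as wild-type. The series' design text lists the groups as the titles do, and it states that male and female samples were analysed separately, which was followed here. The 12 libraries of each sex were fitted together with 1 mean per group, and the 24 libraries were fitted together only to test differences between the sexes.

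Differential expression was tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with TMM scaling, edgeR's group-wise expression filter and robust dispersion fitting. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a fold change of at least 2. Group levels are given in CPM by the cpm function of edgeR with TMM-scaled totals, as mean ± SD over n = 3 libraries, and log2 fold changes as estimate ± SE. The SE is approximate: it was worked back as the absolute log2 fold change divided by the square root of the F statistic. Gene lists were tested with limma's camera (limma 3.58.1) on voom-transformed counts with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Member counts use an adjusted p under 0.05 with no fold threshold. The comparisons, the tests, the 40 gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where the text says otherwise.

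The rule for naming genes took the 6 largest increases and the 6 largest decreases per comparison among protein-coding genes with an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups. Predicted genes, clone names and antigen receptor segments were left out. Sct, Sctr, Cftr, Slc4a2, Tgfbr2, Cdkn1a, Krt19 and Epcam were always included, as were up to 4 members of each list described and 5 sex-linked genes as a check of the labels. For interactions and sex differences the rule took 4 genes in each direction, and the condition on overlap, which is defined for a pair of groups, was not applied. Of the list members that the rule gave, the text names a part that was chosen after the values were seen, mostly members whose call held without any 1 library. Of the largest changes that the rule gave, 1 gene is not reported here.

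Libraries were compared pairwise by the chi-square per gene after thinning each to 1400000 counts, over genes with a summed count of at least 10, where a value of 1 is the sampling noise of repeat sequencing. Sums of marker genes, in CPM of the library total, for heart muscle, neurons, placenta and stratified squamous epithelium were added after the data were seen. The correlation of changes between both contrasts was compared with 20 simulations of unchanged groups, since both contrasts use the dnTGFB libraries. The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors within edgeR, library totals without further scaling, no low-count filter, a stricter filter of 5 CPM in 3 libraries, no fold threshold, a fit of only the compared groups, the replicate number as a block, and leaving out each library in turn. Fits without 6 libraries that stood apart and without the mitochondrially encoded genes were added after seeing the data. Without the 6 libraries, female WT secretin is library 1 alone and female dnTGFB is library 3 alone, and edgeR takes the spread from the other groups, so each lone library is assumed to vary like them. Tables and figures were made with Python 3.11.15.

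The tests were tested on simulated data drawn from a common mean per gene, the fitted dispersions and the libraries' depths, with 100 genes changed by 4-fold and 100 by 8-fold. The changed genes were drawn among the more strongly expressed ones. For male dnTGFB against male WT, over 18604 genes, edgeR recovered 83 of the 4-fold and 96 of the 8-fold changes with 5 false calls. For female dnTGFB against female WT, over 19761 genes, it recovered 33 and 71 with 3 false calls. For the sex difference in the dnTGFB effect, over 20099 genes, it recovered 37 and 56 with 8 false calls. Simulated genes varied independently, so no simulated library differed in tissue content as the real ones did. These figures do not show how the tests behave with such differences.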

Results

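The transcriptomes of intrahepatic cholangiocytes were measured in 24 libraries, in 8 groups of 3: male and female WT mice, WT mice given secretin, dnTGFB mice and dnTGFB mice given secretin. Secretin, a gut hormone that stimulates bicarbonate secretion by bile duct cells, was delivered by implanted osmotic minipumps at 4 µg per kg of body weight per day for 8 weeks, with a second pump after 1 month. Untreated WT mice were killed at 32 weeks of age and secretin-treated mice at 40 weeks, so each effect of secretin against untreated WT includes 8 weeks of age. The age of the untreated dnTGFB mice is not given in the sources used here.

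Total counts ranged from 15225605 to 30203330 in 11 of the 12 male libraries, while male dnTGFB library 3 held 1429218. Female libraries were less even, with 6483182 to 10261421 counts in WT, 13531915 to 104003184 in WT secretin, 35338368 to 100248480 in dnTGFB and 25423691 to 50136106 in dnTGFB secretin. After filtering, 18777 genes were tested in males, 19882 in females and 20222 over both sexes.

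Libraries of 1 group did not always hold the same tissue markers. Female WT secretin libraries 2 and 3 and female dnTGFB libraries 1 and 2 carried heart muscle transcripts, among them the myosin gene Myh6 and the troponin gene Tnnt2, summing to 75338, 81208, 71988 and 73918 CPM, against at most 3684 CPM in the other 8 female libraries. The Y-linked gene Ddx3y stood at 64.31, 59.1, 46.79 and 58.29 CPM in these 4 libraries and at no more than 6.02 CPM in the other female libraries. Male dnTGFB library 3 had a heart muscle sum of 21911 CPM and a neuronal sum of 8657 CPM, with Snap25, a synaptic gene, at 2862 CPM. In male WT library 1 the mitochondrially encoded share of counts was 42.75%, against 9.73% and 9.75% in WT libraries 2 and 3, and hepatocyte markers summed to 16434 CPM against 4495 and 4378 CPM. Xist, the transcript of the inactive X chromosome, was present in the male WT secretin libraries at 33.98 to 42.43 CPM.

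**Figure D1:**
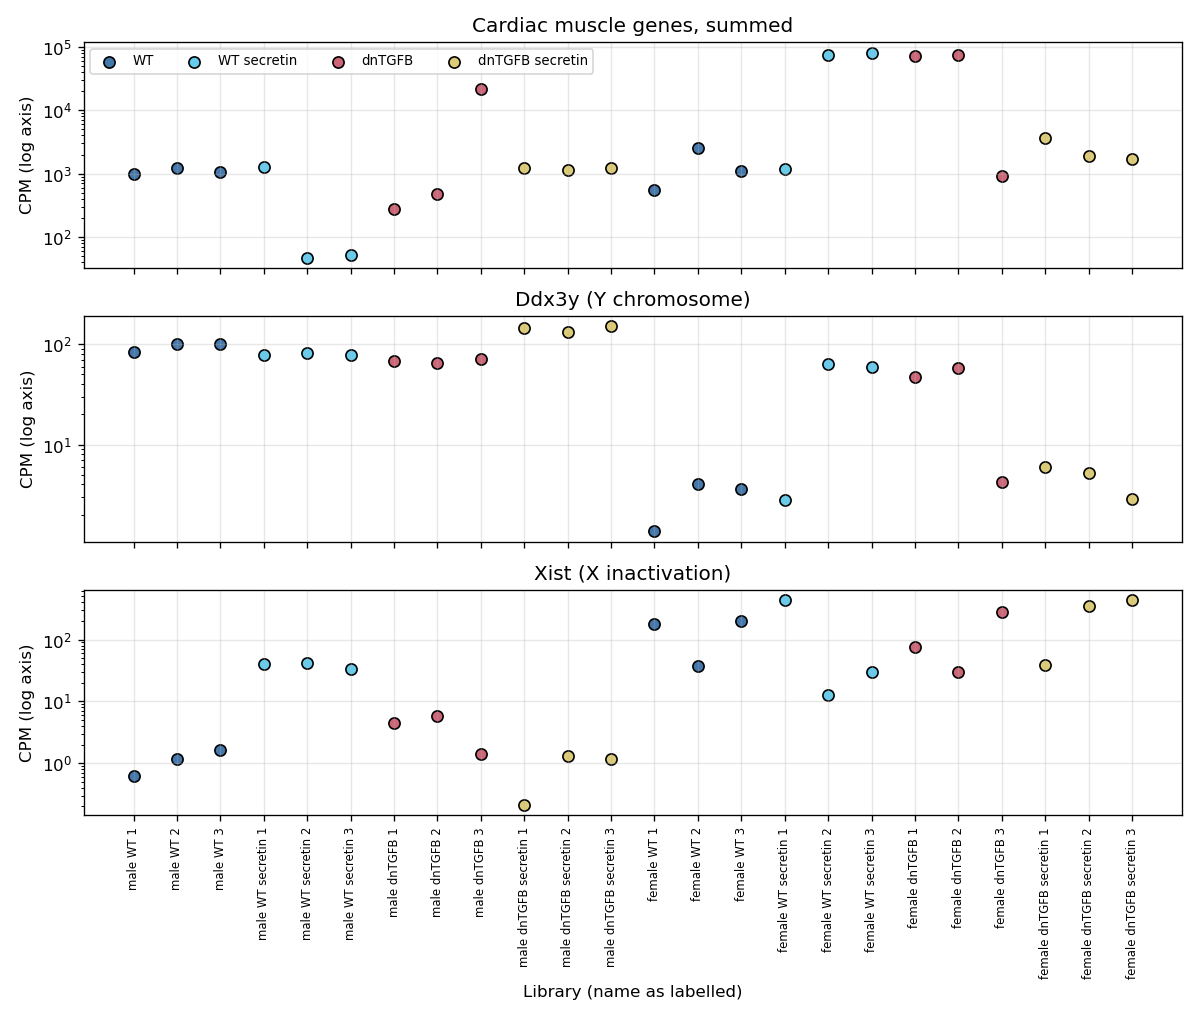
Summed heart muscle transcripts, the Y-linked gene Ddx3y and the X-inactivation transcript Xist in each of the 24 libraries (CPM of the library total, log axes), 1 point per library, by sex and group. The 4 female libraries with 71988 to 81208 CPM of heart muscle transcripts also have Ddx3y at 46.79 to 64.31 CPM, and the male WT secretin libraries have Xist at 33.98 to 42.43 CPM.

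Pairwise comparison placed 10 of the 12 male libraries, but 6 of the 12 female libraries, nearest to a library of their own group. Female WT library 2 was nearest to female dnTGFB secretin library 1, with a chi-square of 1.16 per gene against 10.55 and 28.82 to the nearest library of their own groups. Female WT secretin library 1 was nearest to female dnTGFB secretin library 3, at 1.42 against 62.68 and 3.97. Male libraries that did not stand apart lay within 1.44 per gene of their nearest replicate and within 1.56 of any replicate. No pair was merged, since the near-identical libraries carry different group labels.

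Tgfbr2, the gene whose dominant-negative form defines the model, lies on chromosome 9 from 116084293 to 116175360 on the minus strand (GRCm38, ENSMUSG00000032440). Male libraries held 130.34, 137.67 and 137.7 TMM-scaled CPM in WT, 168.01, 172.43 and 166.85 in WT secretin, 122.67, 125.72 and 37 in dnTGFB, and 108.45, 109.35 and 119.43 in dnTGFB secretin. Female libraries held 109.88, 90.53 and 104.51 in WT, 133.12, 81.7 and 74.93 in WT secretin, 70.3, 66.87 and 98.77 in dnTGFB, and 100.8, 94.61 and 129.28 in dnTGFB secretin. The counts per gene do not separate transcripts of a transgene from those of the endogenous gene, so these values do not check the genotype.

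The genes of the secretin axis were reported in every comparison: Sct, encoding secretin (chromosome 7, 141278330 to 141279133, minus strand, ENSMUSG00000038580), its receptor Sctr (chromosome 1, 120006894 to 120063536, plus strand, ENSMUSG00000026387), the chloride channel gene Cftr (chromosome 6, 18170687 to 18322768, plus strand, ENSMUSG00000041301) and the chloride-bicarbonate exchanger gene Slc4a2 (chromosome 5, 24423837 to 24440950, plus strand, ENSMUSG00000028962). They were set beside the bile duct markers Krt19 (chromosome 11, 100140810 to 100148665, minus strand, ENSMUSG00000020911) and Epcam (chromosome 17, 87635979 to 87651106, plus strand, ENSMUSG00000045394), and beside the cell cycle inhibitor gene Cdkn1a (chromosome 17, 29090979 to 29100722, plus strand, ENSMUSG00000023067). Sct was expressed at a low level, between 0.07 and 6.61 TMM-scaled CPM over all libraries.

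In males, the dnTGFB libraries had lower bile duct and B cell transcripts than the WT libraries. Krt19, a keratin of bile duct epithelium, was 75.7 ± 26.5 CPM in dnTGFB and 229 ± 64.4 CPM in WT (log2 −1.58 ± 0.28, adjusted p = 0.00587), and Epcam was 48.8 ± 12.8 against 170 ± 43.4 CPM (log2 −1.78 ± 0.24, adjusted p = 0.00346). Of 26 biliary identity genes, 22 fell, both over all genes tested and adjusted over the list alone, with Cldn7 at −2.04 ± 0.24, Elf3 at −1.90 ± 0.28 and Spp1, encoding osteopontin, at −1.87 ± 0.25. Of 15 B cell and plasma cell markers, 14 fell (14 adjusted over the list alone): the B cell receptor genes Cd79a, 3.7 ± 3.36 against 81.2 ± 26 CPM, and Cd79b fell by 4.21 ± 0.44 and 4.05 ± 0.34. The list medians were −1.26 for biliary and −3.19 for B cell genes, with camera adjusted p = 1.47e-13 and 1.91e-13, and adjusted p = 0.519 for each with an estimated correlation. Mitochondrially encoded genes took 55.07%, 55.03% and 11.44% of the counts in the dnTGFB libraries and 42.75%, 9.73% and 9.75% in the WT libraries.

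Junction, macrophage and replication genes were also lower in male dnTGFB. Of 20 tight junction and polarity genes 13 fell and 2 rose (14 and 2 adjusted over the list alone), Cldn6 by 2.16 ± 0.35 and Crb3 by 1.63 ± 0.32. Of 18 macrophage and Kupffer cell markers 9 fell (11 over the list alone), among them the Kupffer cell lectin gene Clec4f at −2.12 ± 0.26 and the complement gene C1qa at −1.50 ± 0.17. Of 25 cell cycle genes 9 fell (11 over the list alone), with the replication helicase gene Mcm6 at −1.43 ± 0.19, and of 33 cytosolic ribosomal protein genes 17 fell (33 over the list alone), with a median of −0.68. Of 10 MHC class II genes 4 fell, over all genes and over the list alone, led by the peptide-loading modifiers H2-Oa at −3.18 ± 0.48 and H2-Ob at −3.04 ± 0.32. By camera the adjusted p was 5.08e-05, 1.76e-05, 9.57e-06, 1.47e-13 and 0.000141 for these lists in that order, and adjusted p = 0.519 for each with an estimated correlation. Counts of H2 genes are uncertain where reads are shared with near-identical copies.

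Pancreatic digestive enzyme genes went both ways between male dnTGFB and male WT. Of 10 acinar markers 4 rose and 1, Ctrb1, fell by 1.23 ± 0.173 (7 and 1 adjusted over the list alone), with the elastase gene Cela3b at 2.74 ± 1.53 against 0.605 ± 0.373 CPM (log2 2.28 ± 0.44, adjusted p = 0.00732). Without WT library 1 and dnTGFB library 3, 9 acinar markers were higher and 1 lower (median 3.06). The acinar sum was not higher, at 33.2, 31.6 and 44.8 CPM in dnTGFB and 39.9, 63.6 and 70.3 CPM in WT. The largest increases over all genes were Rph3a, encoding a synaptic vesicle protein (log2 7.57 ± 0.89, adjusted p = 0.00209), Galnt9 at 7.28 ± 0.93, Slc24a2 at 6.94 ± 0.87, Otud7a at 6.72 ± 1.17, Syt6 at 6.71 ± 1.13 and Adgrb1 at 6.70 ± 0.91. These 6 genes were highest in dnTGFB library 3, which had a neuronal sum of 8657 CPM. In dnTGFB libraries 1, 2 and 3 Rph3a stood at 83.44, 50.4 and 525.06 CPM, Galnt9 at 12, 14.45 and 117.46, Slc24a2 at 12.35, 14.55 and 98.67, Otud7a at 4.15, 2.59 and 39.94, Syt6 at 5.54, 2.87 and 38.76 and Adgrb1 at 15.58, 12.97 and 119.22 CPM. Without the libraries that stood apart their log2 fold changes were 5.91, 5.39, 5.51, 4.13, 5.95 and 4.95, each still called. The neuronal sums of dnTGFB libraries 1 and 2 were also higher, at 528.5 and 523.6 CPM against 71.7, 127.8 and 142.5 CPM in WT. The calls that remained are thus not separated from neuronal content. The largest decreases besides Cd79a and Cd79b were of Tubb1 at −4.59 ± 0.64, Ppbp at −3.97 ± 0.42 and Treml1 at −3.44 ± 0.55 and of the B cell factor gene Spib at −3.73 ± 0.35. Ppbp was 60.01, 100.11 and 105.91 CPM in the WT libraries and at most 8.31 CPM in all other male libraries. Cd79a was 51.19, 95.22 and 97.09 CPM in WT and at most 23.06 CPM in the others. All comparisons with male WT share this pool, so these decreases are not separated from its content. Glycolysis genes rose in 4 of 18 (8 over the list alone) and mesothelial markers in 2 of 6 (3 over the list alone). In dnTGFB libraries 1, 2 and 3 the mesothelial marker Gpm6a was 71.09, 73.1 and 415.82 CPM, whereas Wt1 was 6.23, 7.69 and 2.94 CPM. Without WT library 1 and dnTGFB library 3, 10 glycolysis genes were higher and 3 lower (median 0.33). In that fit 3 mesothelial markers were higher and 0 lower (median 1.3). The camera test of the acinar, glycolysis and mesothelial lists gave adjusted p = 0.000796, 0.000333 and 0.0107, and adjusted p = 0.519 for each with an estimated correlation.

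Hepatocyte transcripts were higher as a list in male dnTGFB, while the libraries within each group disagreed. The 25 hepatocyte markers had a median of 1.28 (camera adjusted p = 0.000166, adjusted p = 0.693 with an estimated correlation) and the 19 genes of bile acid synthesis and export a median of 1.17 (2.57e-05 and 0.519), yet edgeR called 0 members of either, with 3 and 7 at an unadjusted p under 0.05. Without WT library 1 and dnTGFB library 3, an alternative chosen after seeing the data, 25 hepatocyte markers rose with a median of 2.90. In the same fit 18 bile acid genes, 15 of 20 T cell markers and 13 of 14 cytotoxic cell markers rose, against 0, 2 and 1 with all libraries, and 1, 1 and 0 fell, while 23 biliary and 14 B cell genes fell and 1 and 0 rose. With all libraries the 13 neutrophil markers had a median of 1.72 and the 13 mitochondrially encoded genes one of 1.42, with 0 members called by edgeR and 2 of each at an unadjusted p under 0.05. Endothelial markers fell in 2 of 16 (8 over the list alone, median −0.96). Without WT library 1 and dnTGFB library 3, 12 of 13 neutrophil markers (median 5.47) and 13 of 13 mitochondrially encoded genes (median 3.45) were higher, and 14 endothelial markers were lower and 2 higher (median −0.69).

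The secretin axis did not pass the test between male dnTGFB and male WT. Sct was 0.982 ± 0.596 against 0.357 ± 0.0983 CPM (log2 1.58 ± 0.51, adjusted p = 0.057), and its adjusted p was 0.0438 without dnTGFB library 1. Sctr differed by 0.01 ± 0.63 (adjusted p = 0.996), but by 1.31 (adjusted p = 0.0241) without WT library 1. Cftr differed by −0.58 ± 0.46, Slc4a2 by −0.20 ± 0.17, Cdkn1a by −0.31 ± 0.43 and Tgfbr2 by −0.49 ± 0.33, with adjusted p = 0.389, 0.413, 0.635 and 0.318. Cdkn1a was 0.16 higher (adjusted p = 0.00903) without the libraries that stood apart. Of 35 secretin and bicarbonate secretion genes 4 rose and 3 fell (9 and 4 over the list alone), with a median of −0.14, a mean of 0.20 and camera direction up (adjusted p = 0.996).

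Few members of the remaining lists passed the test between male dnTGFB and male WT with all libraries. Members passing the test were 2 lower of 23 TGF-β genes (2 adjusted over the list alone, median −0.24), 2 lower of 13 angiogenic factors (2, median −0.45), 2 lower of 10 dendritic cell markers (2, median 0.06, mean −0.12), 1 lower of 26 matrix genes (1, median 0.29) and 2 higher and 1 lower of 18 stellate cell and fibroblast markers (2 and 1, median 0.55). Of 29 inflammatory genes 1 was higher and 2 were lower (1 and 2), as in 20 senescence genes (1 and 2, median −0.02, mean 0.07), and 1 of 24 type I interferon response genes was lower (0 over the list alone). Of 20 Notch and YAP genes 2 were lower (1), as were 2 of 22 primary cilium genes (1) and 2 of 20 cholesterol synthesis genes (0, median 0.14). A single member was higher among 23 immediate-early genes (1, median −0.73), 28 oxidative phosphorylation genes (0, median 0.93), 12 male-biased (1) and 6 female-biased hepatocyte genes (1), and 1 was higher and 1 lower among 18 genes of the unfolded protein response (1 and 1). No member passed edgeR's test among 23 interferon gamma response genes (1 at an unadjusted p under 0.05), 16 MHC class I genes (0), 6 mast cell markers (0), 6 erythroid markers (0) and 10 genes of biliary bile acid transport (4). Without WT library 1 and dnTGFB library 3 more members passed: 19 interferon gamma response genes were higher and 3 lower, 20 matrix genes higher and 3 lower, 14 stellate cell and fibroblast markers higher and 1 lower, 19 inflammatory genes higher and 4 lower, and 5 immediate-early genes higher and 16 lower. Higher and lower were 13 and 2 cholesterol synthesis genes, 13 and 3 type I interferon response genes and 9 and 1 MHC class I genes, with medians of 0.46, 0.32 and 0.17 against 0.14, −0.20 and −0.29 with all libraries.

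In total 2223 genes were called between male dnTGFB and male WT, 1459 higher and 764 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The libraries of both groups did not overlap in 32.7% of genes, where chance gives 10%. Scaling by library totals alone moved the median of all genes from 0.01 to −0.44 and turned the split to 1006 higher and 3233 lower, and the fit of only these 6 libraries called 0 genes, so that the calls rest on the spread of all 12 male libraries. Leaving out WT library 2 gave 1103 calls and leaving out WT library 3 gave 1064, while 3823 were called without the libraries that stood apart. Under library totals the median of the extracellular matrix, interferon gamma, cholesterol, dendritic cell and inflammatory lists changed sign, whereas the biliary median was −1.87 and the B cell median −3.71.

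Secretin in male WT mice went with fewer interferon-response transcripts and more transcripts of mesothelial, matrix and myeloid cells. The WT secretin libraries held Xist at 33.98 to 42.43 CPM, against at most 1.64 CPM in male WT. The changes in this comparison are therefore not separated from female RNA in these libraries. The chemokine gene Cxcl10 was 110 ± 4.17 CPM with secretin and 1500 ± 130 CPM without (log2 −3.77 ± 0.51, adjusted p = 0.00241), and Cxcl11 fell by 3.49 ± 0.47. Of 23 interferon gamma response genes 7 fell (8 adjusted over the list alone), as did 7 of 24 type I interferon response genes (9 over the list alone), with medians of −1.08 and −0.48. Of 6 mesothelial markers 5 rose (5 over the list alone), the leucine-rich repeat gene Lrrn4 by 4.38 ± 0.64 and the transcription factor gene Wt1 by 2.58 ± 0.37. The interferon lists had camera adjusted p = 1.76e-06 and 5.28e-05, each with adjusted p = 0.695 with an estimated correlation. For the mesothelial list it gave 1.23e-06, and this was the only camera call over all comparisons that held with an estimated correlation (adjusted p = 0.0252).

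Myeloid and matrix genes rose together with pancreatic enzymes in male WT secretin. Of 18 macrophage markers 6 rose (10 over the list alone), with the chemokine receptor gene Ccr2 at 3.36 ± 0.34 and the lysozyme gene Lyz2 at 2.00 ± 0.18, and of 10 dendritic cell markers 6 rose (6 rose and 1 fell over the list alone), with Itgax at 3.01 ± 0.42. Cd209a, a dendritic cell lectin gene, was 18.4 ± 1.76 CPM with secretin (log2 5.55 ± 0.37, adjusted p = 6.95e-05). Of 26 matrix genes 10 rose (13 over the list alone, median 1.15), with the collagenase gene Mmp2 at 2.49 ± 0.39. Of 10 acinar markers 8 rose (9 over the list alone, median 3.64), with Cela3b at 9.98 ± 0.858 against 0.605 ± 0.373 CPM, Cela2a at 3.95 ± 0.52 and Prss2 at 3.73 ± 0.54. The carboxypeptidase gene Cpb1, which is not in that list, rose by 4.18 ± 0.40. The acinar rise is not separated from female RNA, since these libraries held Xist and the female WT libraries held acinar sums of 941.3 to 1304.8 CPM. Macrophage markers summed to 4849.1, 1027.9 and 1280.5 CPM in female WT libraries 1, 2 and 3. Their sum was 1777.6 to 1846.1 CPM in male WT secretin and 524.1 to 1046.2 CPM in male WT. The macrophage rise is thus not separated from female RNA either. Camera gave adjusted p = 1.52e-07, 1.47e-05, 3.66e-06 and 1.21e-10 for these lists, with adjusted p = 0.387, 0.271, 0.695 and 0.197 with an estimated correlation.

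Some B cell and cholesterol synthesis genes were lower in male WT secretin. Of 15 B cell markers 7 fell (11 over the list alone, camera adjusted p = 3.66e-06, adjusted p = 0.587 with an estimated correlation), with Cd79a at −1.85 ± 0.38, whose adjusted p of 0.0167 became 0.0775 to 0.0865 without any 1 of 5 libraries. Of 20 cholesterol synthesis genes 6 fell (7 over the list alone, camera adjusted p = 0.000134, adjusted p = 0.695 with an estimated correlation), with Hmgcs1, encoding the cytosolic HMG-CoA synthase, at −1.34 ± 0.19. Tubb1 fell by 4.94 ± 0.57, Ppbp by 4.81 ± 0.42, Treml1 by 4.66 ± 0.54, Gp9 by 4.66 ± 0.53 and the cornified envelope gene Sprr1a by 4.77 ± 0.43. Tubb1, Ppbp, Treml1 and Cd79a were also lower in dnTGFB against the same WT pool, so their falls are not separated from the content of that pool. The largest increases were A1bg at 6.25 ± 0.74 and Calca, the calcitonin gene, at 6.09 ± 0.80. Xist rose by 4.92 ± 0.61 (adjusted p = 0.00137).

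Hepatocyte genes did not pass the test between male WT secretin and male WT with all libraries, and a few dissociation-response genes did. Hepatocyte markers summed to 20781 to 21805 CPM with secretin and to 16434, 4495 and 4378 CPM in WT libraries 1, 2 and 3. With all libraries edgeR called 0 of the 25, with 0 at an unadjusted p under 0.05, while without the libraries that stood apart, where WT library 1 and dnTGFB library 3 were left out together, 23 were higher and 1 lower (median 1.15). Of 23 immediate-early and dissociation response genes 4 fell and 1 rose (5 and 1 over the list alone, median −0.55, camera adjusted p = 0.0226, adjusted p = 0.784 with an estimated correlation), and 18 were lower and 3 higher without the libraries that stood apart. The heat shock gene Hspa1b fell by 3.22 ± 0.685 (adjusted p = 0.0201), a call that ended without WT library 2 (0.0687) or 3 (0.0728) or WT secretin library 1 (0.0966), 2 (0.0998) or 3 (0.0905).

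Krt19, Epcam and the genes of the secretin axis did not pass the test in male WT secretin with all libraries, and Cdkn1a did. Tgfbr2 differed by 0.32 ± 0.33, Krt19 by −0.35 ± 0.28, Epcam by −0.53 ± 0.23, Sct by −0.51, Cftr by 0.73 ± 0.42 and Slc4a2 by 0.56 ± 0.16, with adjusted p from 0.0731 to 0.647. Sctr was 5.28 ± 1.43 against 1.92 ± 2.0 CPM (log2 1.47 ± 0.56, adjusted p = 0.156), and its adjusted p was 0.00143 at a log2 fold change of 2.78 without WT library 1. Cdkn1a fell by 1.88 ± 0.44 (adjusted p = 0.0309), a call lost without any 1 of the 6 libraries (adjusted p from 0.0638 to 0.128). Of 26 biliary genes 3 rose and 2 fell (5 and 3 over the list alone), with a median of −0.13 and camera direction up (adjusted p = 0.913), while 9 were higher and 14 lower (median −0.30) without the libraries that stood apart.

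Between male WT secretin and male WT 803 genes were called, 516 higher and 287 lower, and 43.4% of genes did not overlap, where chance gives 10%. The count was 833 without WT library 1, but 295 to 336 without any other single library of the comparison, and 2321 without the libraries that stood apart. Library totals moved the median of all genes from 0 to 0.19 and moved the share called higher from 64.3% to 76.1%.

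Secretin in male dnTGFB mice went with higher bile duct genes and lower hepatocyte and mitochondrial genes. Krt19 was 361 ± 8.75 CPM with secretin and 75.7 ± 26.5 CPM without (log2 2.24 ± 0.29, adjusted p = 0.000859), and Epcam rose by 2.61 ± 0.24 to 301 ± 4.61 CPM (adjusted p = 0.000136). Of 26 biliary genes 24 rose (24 adjusted over the list alone, median 1.88), with Cldn7 at 3.02 ± 0.25, Spp1 at 2.71 ± 0.26 and the mucin gene Muc1 at 2.62 ± 0.24. Of 20 junction genes 14 rose and 1 fell (16 and 2 over the list alone), with the pore-forming claudin gene Cldn2 at 2.15 ± 0.23. Camera gave adjusted p = 3.25e-20 and 4.3e-08, and adjusted p = 0.312 and 0.512 with an estimated correlation. Over the same libraries the mitochondrially encoded share of counts was 5.31% to 5.66% with secretin and 55.07%, 55.03% and 11.44% without.

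The receptor and channel genes of the secretin axis rose with secretin in male dnTGFB, as the bile duct genes did. Biliary genes summed to 1411.8 to 1514.1 CPM in dnTGFB and to 11866.6 to 12024.6 CPM with secretin. The rise of Sctr and Cftr is therefore not separated from more bile duct RNA per library. Sctr was 12.4 ± 1.01 against 1.87 ± 0.222 CPM (log2 2.70 ± 0.63, adjusted p = 0.0165), a call that ended without dnTGFB secretin library 1 (adjusted p = 0.0528) or 2 (0.0543). Cftr was 16.2 ± 0.959 against 2.4 ± 2.08 CPM (log2 2.46 ± 0.46, adjusted p = 0.0068), and Slc4a2 differed by 0.41 ± 0.17 (adjusted p = 0.0953, and 0.0437 without dnTGFB library 2). Sct fell by 2.39 ± 0.53 (adjusted p = 0.0136), a call that ended without dnTGFB library 2 (0.0711), without dnTGFB secretin library 1 (0.0718), 2 (0.0547) or 3 (0.0662), and under library totals (0.0875). Tgfbr2 differed by 0.22 ± 0.33 (adjusted p = 0.657) and by −0.14 (0.0342) without the libraries that stood apart. Cdkn1a differed by −0.21 ± 0.43 (adjusted p = 0.747) but by −0.64 (3.49e-06) without dnTGFB library 3. Of 35 secretin and bicarbonate secretion genes 8 rose and 6 fell (9 and 8 over the list alone).

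Macrophage and acinar genes rose and hepatocyte genes fell with secretin in male dnTGFB. Of 18 macrophage markers 13 rose (16 over the list alone), with C1qa at 2.05 ± 0.18 and Clec4f at 2.21 ± 0.26, and of 10 acinar markers 7 rose (9 over the list alone), with the chymotrypsinogen gene Ctrb1 at 3.07 ± 0.18. Of 25 hepatocyte markers 10 fell (17 over the list alone, median −2.06), with the tryptophan dioxygenase gene Tdo2 at −2.36 ± 0.42. Of 19 bile acid synthesis and export genes 13 fell (16 over the list alone), and 10 of 12 male-biased hepatocyte genes fell while 1 rose (10 and 1 over the list alone), with Mup20 at −2.41 ± 0.23. All 13 mitochondrially encoded genes fell (13 over the list alone), with mt-Co3 at −4.01 ± 0.80. In that order the camera adjusted p was 3.37e-11, 4.3e-08, 5.52e-06, 1.04e-07, 4.01e-07 and 1.14e-07, with adjusted p = 0.312, 0.312, 0.715, 0.584, 0.312 and 0.584 with an estimated correlation. Hepatocyte markers summed to 22326, 21356 and 5529 CPM in the dnTGFB libraries and to 7167 to 7201 CPM with secretin. Without the libraries that stood apart 25 hepatocyte, 16 of 20 T cell, 12 of 14 cytotoxic and 12 of 13 neutrophil markers were lower and 0 higher. In that fit 21 of 26 matrix genes were lower and 3 higher, and 17 macrophage markers were higher and 0 lower.

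The largest increases were Shh, encoding the ligand Sonic hedgehog, at 23.4 ± 0.268 against 1.83 ± 0.79 CPM (log2 3.77 ± 0.34, adjusted p = 0.000117), and Slpi, a secreted protease inhibitor gene, at 684 ± 30.1 against 51.4 ± 12 CPM (log2 3.75 ± 0.24, adjusted p = 1.98e-05). The anion exchanger gene Slc26a3 rose by 3.74 ± 0.33, the carbonic anhydrase gene Car9 by 3.61 ± 0.27, the mucin glycosyltransferase gene Gcnt3 by 3.60 ± 0.60 and Etv4 by 3.60 ± 0.46. The largest decrease was of mt-Nd3, at −6.07 ± 1.29 (adjusted p = 0.0119), a call lost without any 1 of the dnTGFB secretin libraries (0.0555 to 0.0613). Psg21, a placental glycoprotein gene whose reads could be shared with near-identical copies, followed at −5.30 ± 1.03. Its level was 15.23, 15.1 and 0.59 CPM in the dnTGFB libraries. Next were Tgm3 at −4.79 ± 1.01, the squamous keratin gene Krt4 at −4.72 ± 1.11, mt-Nd2 at −4.71 ± 1.10 and mt-Nd4l at −4.54 ± 1.09, with calls lost without dnTGFB secretin library 2 or 3 for Tgm3 (adjusted p = 0.0593 and 0.0549) and without any 1 of these libraries for the others (0.0576 to 0.0768). Counts of Mup20, Try5, Prss2, Psg28, Serpina1e and Cyp4a12b, like those of Psg21, are uncertain because reads could be shared with near-identical copies. Squamous epithelium transcripts summed to 345.3, 359.7 and 57.4 CPM in the dnTGFB libraries and to 31.1 to 46.2 CPM with secretin. The falls of Tgm3 and Krt4 are thus not separated from this content.

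**Figure D2:**
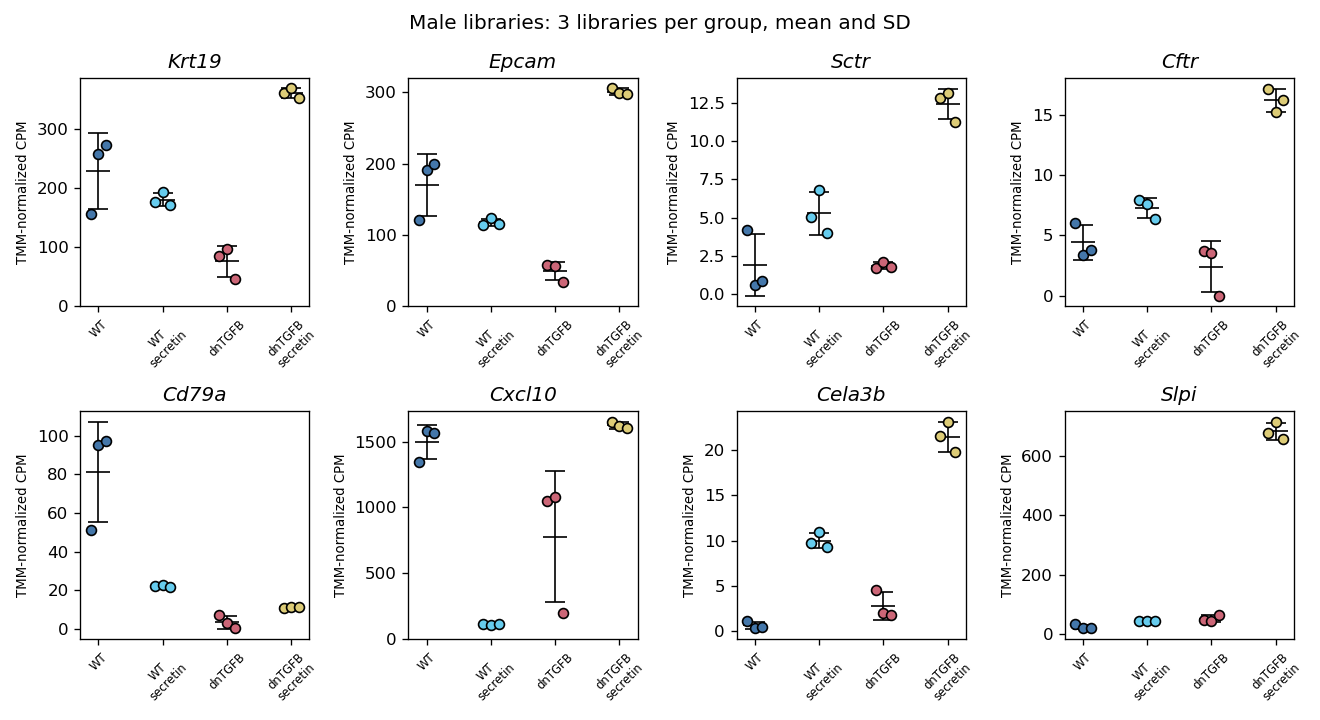
TMM-scaled CPM of Krt19, Epcam, Sctr, Cftr, Cd79a, Cxcl10, Cela3b and Slpi in the 4 male groups, with 1 point per library and the mean with its SD (n = 3). Krt19 averaged 75.7 CPM in dnTGFB and 361 CPM in dnTGFB secretin, and Cd79a averaged 81.2 CPM in WT and at most 22.5 CPM in the other groups.

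Between male dnTGFB secretin and male dnTGFB 3041 genes were called, 1030 higher and 2011 lower, and 41.1% of genes did not overlap, where chance gives 10%. Scaling by library totals moved the median of all genes from −0.05 to 0.75 and turned the split to 87.6% of calls higher, from 33.9%. The count fell to 868 to 972 without any 1 of the dnTGFB secretin libraries and to 500 in the fit of only these 6 libraries. Under library totals the medians of the biliary, hepatocyte and mitochondrially encoded lists were 2.82, −1.07 and −2.85.

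Of the 2223 genes called between male dnTGFB and male WT, 1435 (64.6%) were called in the opposite direction between dnTGFB secretin and dnTGFB, and 32 in the same direction. Of the opposite calls 1029 were higher in dnTGFB and then lower with secretin, where independent lists give 156.3, and 406 were lower and then higher, where independent lists give 41.9. The dnTGFB secretin mean lay within 1.5-fold of WT for 823 of the 2223 genes (37%). Both contrasts share the 3 dnTGFB libraries, which are too few to split, so the contrasts are not independent. In 20 simulations of unchanged groups the correlation of fold changes across genes had a median of −0.62 and a covariance of −0.18, against −0.76 and −1.28 observed. The simulated groups gave too few calls to set a level for opposite calls, so a shift of the shared dnTGFB libraries alone is not excluded. Genes are not independent replicates. Without the libraries that stood apart 2199 of 3823 genes (57.5%) were called in the opposite direction.

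Male dnTGFB mice given secretin were also compared with untreated male WT mice. The dnTGFB secretin libraries held more transcripts of pancreatic enzymes and fewer of B cells and male-biased hepatocyte genes. All 10 acinar markers rose (10 adjusted over the list alone, median 3.89), with Try5, a trypsinogen gene, at 5.29 ± 0.46 and Cela3b at 21.5 ± 1.65 against 0.605 ± 0.373 CPM (log2 5.15 ± 0.43, adjusted p = 8.86e-05). Slpi rose by 4.80 ± 0.26 (adjusted p = 8.88e-06), Rph3a by 4.59 ± 0.79, Reg1 by 4.30 ± 0.44 and Cpa1 by 4.12 ± 0.48. Neuronal sums were 459.8 to 545.6 CPM in dnTGFB secretin and 71.7 to 142.5 CPM in WT. The rise of Rph3a is thus not separated from neuronal content. Of 15 B cell markers 11 fell and 2 rose (11 and 2 over the list alone), with the transcription factor gene Pax5 at −5.13 ± 0.45, and the IgM receptor gene Fcmr fell by 5.11 ± 0.53. Of 12 male-biased hepatocyte genes 9 fell (10 fell and 1 rose over the list alone), with the steroid dehydrogenase gene Hsd3b5 at −2.90 ± 0.45. Camera gave adjusted p = 1.97e-16, 4.03e-09 and 1.04e-08 for these lists, with adjusted p = 0.12, 0.415 and 0.12 with an estimated correlation.

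Some biliary genes were higher in male dnTGFB secretin than in WT. Of the 26 genes 6 rose, or 24 (median 0.52) without the libraries that stood apart (with all libraries 11 over the list alone, median 0.65, camera adjusted p = 4.03e-09, adjusted p = 0.539 with an estimated correlation), whereas Krt19 differed by 0.66 ± 0.28 (adjusted p = 0.22) and Epcam by 0.82 ± 0.23 (adjusted p = 0.0731). Of 20 junction genes 4 rose (4 over the list alone, camera adjusted p = 0.000781, adjusted p = 0.764 with an estimated correlation), with Cldn2 at 1.80 ± 0.22. Sctr rose by 2.70 ± 0.57 (adjusted p = 0.0227) and Cftr by 1.88 ± 0.42 (adjusted p = 0.0307), and both calls ended without WT library 2 or 3 or any 1 of the dnTGFB secretin libraries, at adjusted p from 0.0647 to 0.0883 and from 0.117 to 0.136. Biliary genes summed to 11866.6 to 12024.6 CPM in dnTGFB secretin and to 3129.9, 7337.1 and 7377.1 CPM in WT. The rise of Sctr and Cftr is therefore not separated from more bile duct RNA per library here either. Tgfbr2 differed by −0.27 ± 0.33 and Cdkn1a by −0.52 ± 0.43, with adjusted p = 0.743 and 0.574. Ppbp and Tubb1 fell by 5.51 ± 0.44 and 5.17 ± 0.57, and Rgs18 by 5.35 ± 0.53. Ppbp and Tubb1 were lower in every comparison with this WT pool, so their falls are not separated from its content.

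Between male dnTGFB secretin and male WT 625 genes were called, 269 higher and 356 lower, and 47% of genes did not overlap, where chance gives 10%. The count was 286 to 421 without any single library other than WT library 1 and 2209 without the libraries that stood apart. With library totals the median of all genes went from −0.01 to 0.33 and the share called higher from 43% to 68.8%.

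**Figure D3:**
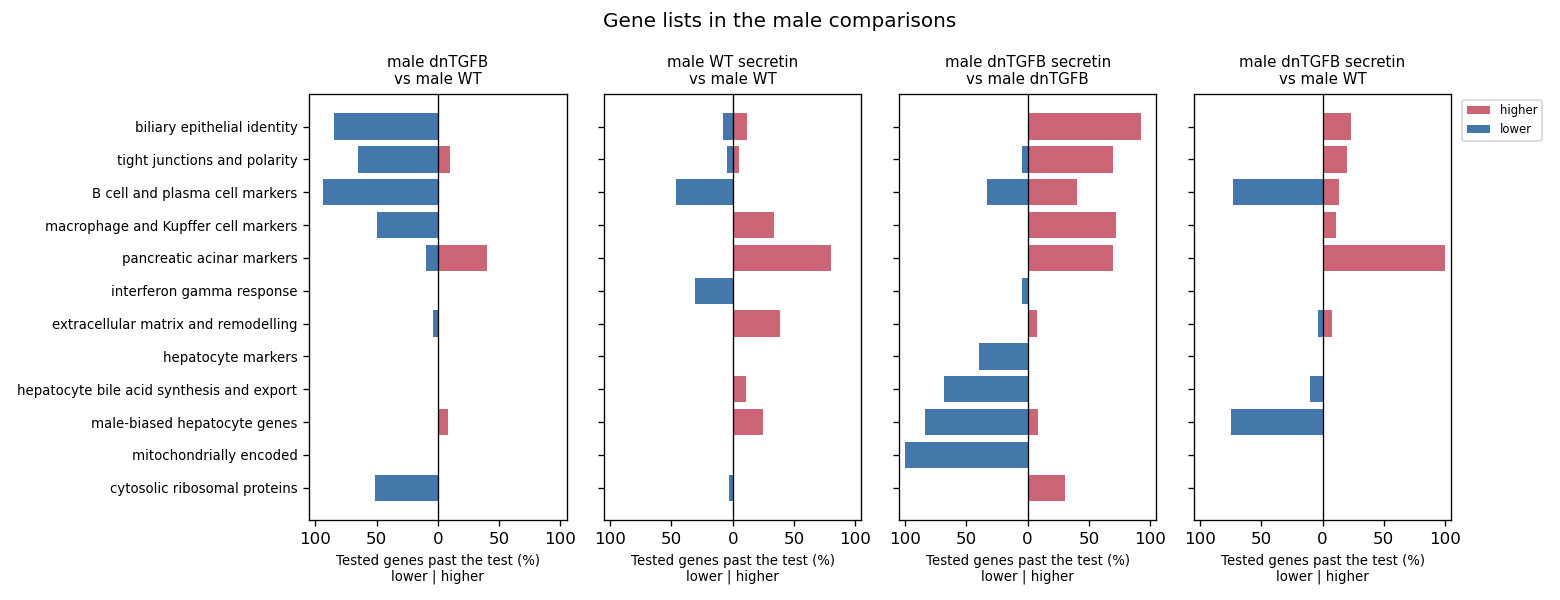
Share of the tested genes of 12 lists that passed the test (adjusted p under 0.05) as higher (right) or lower (left) in each of the 4 male comparisons, in percent. Of 26 biliary genes 22 were lower in dnTGFB than in WT and 24 were higher with secretin in dnTGFB. Medians of the matrix, interferon gamma and male-biased hepatocyte lists change sign under library totals between dnTGFB and WT.

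The male interaction tested whether secretin acted differently in dnTGFB and in WT mice. It uses the WT secretin libraries, which held Xist, so its terms are not separated from female RNA in them. The difference was positive for 20 of 26 biliary genes and negative for 1 (20 and 2 adjusted over the list alone, median 2.20), with Cldn7 at 3.80 ± 0.34 and Epcam at 3.14 ± 0.33. It was positive for 18 of 33 ribosomal protein genes (31 over the list alone), 6 of 23 interferon gamma response genes (7), and 8 of 20 cholesterol synthesis genes (11), with Cxcl11 at 3.22 ± 0.62 and Cyp51, a sterol demethylase gene, at 1.84 ± 0.34. It was negative for 10 of 12 male-biased hepatocyte genes (10 negative and 1 positive over the list alone), with Mup20 at −4.58 ± 0.32, and for 5 of 6 mesothelial markers (6), with Lrrn4 at −5.19 ± 0.96. In that order camera gave adjusted p = 1.3e-12, 1.3e-12, 0.000209, 0.026, 7e-08 and 6.84e-05. With an estimated correlation these were adjusted p = 0.701, 0.701, 0.702, 0.712, 0.155 and 0.0853.

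Sprr1a had the largest positive interaction, 6.19 ± 0.56 (adjusted p = 0.000251), from 32.1 ± 5.18 to 1.18 ± 0.21 CPM in WT and from 14.8 ± 9.33 to 43 ± 2.35 CPM in dnTGFB. Cxcl10, which fell in WT, was 778 ± 500 CPM in dnTGFB and 1630 ± 25.4 CPM with secretin (interaction 4.83 ± 0.69, adjusted p = 0.00209), and Cldn4 and Arl14 followed at 4.61 ± 0.51 and 4.52 ± 0.54. The largest negative interaction was of A1bg, a female-biased hepatocyte gene, at −11.47 ± 1.08 (adjusted p = 0.000281). A1bg was 6.86, 11.09 and 12.81 CPM in the WT secretin libraries and 4.39, 1.39 and 0 CPM in the dnTGFB libraries, against at most 0.2 CPM in the other male groups. Xist was 35.14, 37.39 and 30.13 CPM in the same WT secretin libraries and 7.96, 10.1 and 1.17 CPM in dnTGFB, against at most 1.45 CPM, so the interaction of A1bg is not separated from female RNA in these libraries. Calca followed mt-Nd3 (−6.95 ± 1.62) at −6.88 ± 1.44, and its adjusted p of 0.0121 became 0.224 without dnTGFB library 1, while that of mt-Nd3 (0.0188) became 0.0559 to 0.0619 without any 1 of the dnTGFB secretin libraries. Cdh11 stood at −5.61 ± 0.89. In total 2435 genes were called, 1126 positive and 1309 negative. Without any 1 of the WT libraries 2 and 3, the WT secretin libraries or the dnTGFB secretin libraries the count was 1073 to 1264, and it was 3793 without dnTGFB library 3. Library totals moved the median of all genes from −0.07 to 0.50 and the positive share from 46.2% to 85.3%.

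In females, no named gene passed the test between dnTGFB and WT. Tgfbr2 differed by −0.37 ± 0.27 (adjusted p = 0.433), Krt19 was 172 ± 142 CPM in dnTGFB and 138 ± 99.1 CPM in WT (log2 0.32 ± 0.90, adjusted p = 0.872), and Sct differed by −3.13 ± 1.41 (adjusted p = 0.257). The Y-linked gene Ddx3y differed by 4.02 ± 1.35 (adjusted p = 0.242). The 28 nuclear genes of oxidative phosphorylation had a median of 2.72 and all passed as higher adjusted over the list alone (camera adjusted p = 2.35e-09, adjusted p = 0.851 with an estimated correlation), while over all genes tested edgeR called 0 and 28 had an unadjusted p under 0.05. Without the 4 libraries with heart muscle transcripts, a fit chosen after seeing the data, their median was −0.10, with library 3 as the only dnTGFB library.

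Secretin in female WT mice gave a similar picture. Tgfbr2 differed by −0.07 (adjusted p = 0.875), Krt19 by −1.23 ± 0.92 (adjusted p = 0.394) and Sct by −3.99 ± 1.5 (adjusted p = 0.152). Adjusted over the list alone, all 25 hepatocyte markers passed as lower (median −3.05, camera adjusted p = 4.74e-22, adjusted p = 0.634 with an estimated correlation) and all 28 oxidative phosphorylation genes as higher (median 2.93, 1.87e-07, and also 0.634), while over all genes tested edgeR called 0 in either list, with 25 and 28 at an unadjusted p under 0.05. Without the 4 libraries with heart muscle transcripts these medians were −1.92 and −0.36, with library 1 as the only WT secretin library.

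Between female dnTGFB secretin and female dnTGFB edgeR called 0 of the 28 oxidative phosphorylation genes over all genes tested, and adjusted over the list alone all 28 passed as lower (median −2.63, camera adjusted p = 2.53e-07, adjusted p = 0.878 with an estimated correlation). The median was 0.12 without the 4 libraries with heart muscle transcripts, which leaves library 3 as the only dnTGFB library. Tgfbr2 differed by 0.46 (adjusted p = 0.353), Krt19 by −0.46 ± 0.91 (0.789) and Sct by 3.36 ± 1.40 (0.266). Between female dnTGFB secretin and female WT, Krt19 differed by −0.14, Epcam by 0.44 and Sct by 0.23, with Epcam and Sct at an adjusted p of 1.0.

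edgeR called 0 genes in each of the 4 female comparisons, and limma-voom also called 0. Unadjusted p under 0.05 was met by 3859 genes between dnTGFB and WT, 5263 between WT secretin and WT, 3626 between dnTGFB secretin and dnTGFB, and 100 between dnTGFB secretin and WT, and DESeq2 called 742, 2418, 431 and 0. Without female WT secretin library 1, edgeR called 4739 genes between WT secretin and WT, where the WT secretin libraries left were those with 75338 and 81208 CPM of heart muscle transcripts. The shares of genes without overlap were 22.9%, 23.7%, 17.6% and 3.6%, where chance gives 10%. Library totals moved the median of all genes from 0.10 to −0.07, from 0.11 to −0.05, from −0.02 to 0.36 and from 0.04 to 0.24 in the 4 comparisons.

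The female interaction of secretin and genotype called 3546 genes, 795 positive and 2751 negative. The largest positive terms were of squamous epithelial and placental genes, Serpinb3a at 13.01 ± 3.06 (adjusted p = 0.0408), Ceacam5 at 11.81, Cnfn at 11.78 and Psg28 at 11.77. Serpinb3a was 68.14 CPM in WT library 2 and 75.03 CPM in dnTGFB secretin library 1, against at most 3.14 CPM in the other female libraries. The largest negative terms were of striated muscle genes, Klhl38 at −11.77 ± 2.50 (adjusted p = 0.0408), Myot at −11.73, Lrrc10 at −11.44 and Mybphl at −11.20. All 28 oxidative phosphorylation genes were negative (28 over the list alone, median −5.56, camera adjusted p = 2.6e-08, adjusted p = 0.81 with an estimated correlation), with Sdhb at −6.58 ± 1.64. Without the 4 libraries with heart muscle transcripts Myot stood at 1.00 and Sdhb at 0.93. That fit called 0 genes, but WT secretin and dnTGFB then hold 1 library each, assumed to vary like the other 2 groups, so the 0 says little. The count was 7818 without WT secretin library 1, 6273 without dnTGFB library 3 and 0 without any other single library, so that the calls of all genes named here ended (adjusted p from 0.0613 to 0.12), and DESeq2 called 5834, limma-voom 0 and the fit on library totals 0, with a median of all genes of 0.46 against −0.07.

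The effect of genotype differed between the sexes in 1310 genes, 413 with a higher and 897 with a lower fold change in females. Female dnTGFB libraries 1 and 2 held heart muscle transcripts and Ddx3y at 46.79 and 58.29 CPM, and male dnTGFB library 3 held heart muscle and neuronal transcripts. The differences are therefore not separated from the content of these libraries. B cell genes fell in males and not detectably in females: 5 of 15 markers had a more positive fold change in females (11 adjusted over the list alone, median 2.85, camera adjusted p = 3.61e-07, adjusted p = 0.727 with an estimated correlation), with Cd79a at 4.47 ± 0.96 (adjusted p = 0.00728) and Cd79b at 4.24 ± 0.78. Without the 6 libraries that stood apart the B cell median was 3.74, with library 3 as the only female dnTGFB library. The largest negative differences were of Rph3a at −11.49 ± 1.95 (adjusted p = 0.00207), Syt6 at −9.52, Galnt9 at −9.43 and Nefm at −8.85. Rph3a was 525.06 CPM in male dnTGFB library 3 against 83.44 and 50.4 CPM in libraries 1 and 2, and 49.26 CPM in female WT library 3 against 1.61 and 1.92 CPM in libraries 1 and 2. The largest positive ones were Slc36a2 at 5.65, Srpk3, a muscle kinase gene, at 5.30 ± 1.35 (adjusted p = 0.0219), Cytl1 at 5.22 and Tcf15 at 4.64, and these 4 calls ended without 1 of at least 4 libraries (adjusted p from 0.0501 to 0.119). Srpk3 was 33.06 and 36.5 CPM in female dnTGFB libraries 1 and 2, which held 71988 and 73918 CPM of heart muscle transcripts, against 1.69 CPM in library 3. Without the 6 libraries that stood apart the difference was 2.00 for Srpk3 (adjusted p = 0.246) and −9.71 for Rph3a (adjusted p = 0.0471), but female dnTGFB is then library 3 alone, assumed to vary like the other groups, so neither value shows whether the difference holds. With DESeq2 size factors 19.9% of calls were more positive in females, against 31.5% with TMM, and the median of all genes was 0.11 against 0.25 (0.48 with library totals). Leaving out female dnTGFB library 3 gave 3177 calls, and leaving out male WT library 2 or 3 gave 817 or 823, female WT library 2 or 3 gave 862 or 818, and female dnTGFB library 1 or 2 gave 771 or 737.

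The effect of secretin in dnTGFB differed between the sexes in 1490 genes, 1071 with a higher and 419 with a lower fold change in females. Macrophage markers had a lower fold change in females in 8 of 18 (13 over the list alone, median −2.68, camera adjusted p = 6.06e-07, adjusted p = 0.938 with an estimated correlation), with C1qa at −3.04 ± 0.60 (adjusted p = 0.023) and the Fc receptor gene Fcgr1 at −3.72 ± 0.87. The macrophage sums disagreed within female dnTGFB, at 1650.1 and 1089.8 CPM in libraries 1 and 2, which held heart muscle transcripts, and 6889.6 CPM in library 3. With library 3 as the only female dnTGFB library, without the 6 libraries that stood apart, the list median was −3.26. Psg21 at 11.42 ± 2.39, Serpinb3a at 11.15, Krtdap at 11.11 and Serpinb12 at 10.90 had the largest positive differences. Within its group female dnTGFB secretin library 1 stood out in these placental and squamous genes, with Psg21 at 166.29 CPM against 3.41 and 2.18 CPM and Serpinb3a at 75.03 against 0.97 and 0.64 CPM in libraries 2 and 3. Male dnTGFB libraries 1 and 2, which enter the same test, had squamous sums of 345.3 and 359.7 CPM. These sums were 57.4 CPM in male dnTGFB library 3 and 31.1 to 46.2 CPM in male dnTGFB secretin. The differences are thus not separated from this content. Ly6i at −6.77, Saa3 at −6.25, Ms4a4a at −5.85 and Slc26a3 at −5.31 ± 0.89 had the largest negative differences. All calls of genes named here ended without any 1 male dnTGFB secretin library (adjusted p from 0.0654 to 0.0816). The count was 1 to 3 without any 1 male dnTGFB secretin library, 3 and 5 without female dnTGFB libraries 1 and 2, 2886 without female dnTGFB library 3, 569 without female dnTGFB secretin library 1 and 1 under library totals, which moved the median of all genes from −0.15 to −0.48. The effect of secretin in WT differed in 0 genes by edgeR, with 4537 at an unadjusted p under 0.05, 1680 called by DESeq2, 247 by limma-voom and 4184 by edgeR without female WT secretin library 1. With library totals its median over all genes was −0.23 against 0.10.

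No gene was called in both sexes in any of the 4 comparisons, since edgeR called 0 genes in females, whereas DESeq2 calls gave 132, 159 and 101 shared genes for dnTGFB against WT, WT secretin against WT and dnTGFB secretin against dnTGFB. Across 18393 genes, which are not independent replicates, the fold changes of both sexes correlated with Pearson's r of 0.01, 0.05, −0.07 and 0.13 in the 4 comparisons and with Spearman's rho of 0.06, 0.09, 0.01 and 0.25.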

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

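All tests of explanations and all regroupings of libraries in this part were chosen after the results had been seen. The results here were picked out because a test of the difference itself, either the interaction of secretin and genotype or the difference between the sexes, passed the threshold.

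The male interaction of secretin and genotype was called for 2435 genes, and it is not separated from female RNA in the WT secretin libraries. The largest positive terms were of Sprr1a (6.19), Cxcl10 (4.83), Cldn4 (4.61) and Arl14 (4.52), and the largest negative terms of A1bg (−11.47), mt-Nd3 (−6.95), Calca (−6.88) and Cdh11 (−5.61). In females the interaction was called for 3546 genes, led by Serpinb3a (13.01), Ceacam5 (11.81), Cnfn (11.78) and Psg28 (11.77), and by Klhl38 (−11.77), Myot (−11.73), Lrrc10 (−11.44) and Mybphl (−11.20).

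The sexes differed in the effect of genotype for 1310 genes, with Slc36a2 (5.65), Srpk3 (5.30), Cytl1 (5.22) and Tcf15 (4.64) more positive in females, and Rph3a (−11.49), Syt6 (−9.52), Galnt9 (−9.43) and Nefm (−8.85) more negative. They differed in the effect of secretin in dnTGFB mice for 1490 genes, with Psg21 (11.42), Serpinb3a (11.15), Krtdap (11.11) and Serpinb12 (10.90) more positive in females, and Ly6i (−6.77), Saa3 (−6.25), Ms4a4a (−5.85) and Slc26a3 (−5.31) more negative. Female dnTGFB libraries 1 and 2, which held heart muscle transcripts, enter both tests, so neither count is separated from their content.

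Chance as the source of these counts was tested by regrouping the same libraries. For the male interaction 1 of 100 groupings, the real one, reached 2435 calls, the highest other being 133. For the sex difference in the effect of genotype 1 of 50 groupings reached 1310 calls, the highest other being 31, and for that in the effect of secretin in dnTGFB 1 of 50 reached 1490, the highest other being 3. The count of 1490 also fell to 1, 3 and 3 without male dnTGFB secretin library 1, 2 or 3 and to 1 under library totals. For the female interaction 6 of 100 groupings reached 3546 calls, the highest other being 6482, and chance could not be excluded; a regrouping with more calls than the real one points to a structure of the libraries other than their group names. For the sex difference in the effect of secretin in WT all 50 of 50 groupings reached its count of 0, as any grouping must, so this tests nothing. Since each group is 1 pool sequenced 3 times, a regrouping mixes pools and sets their difference against the spread between libraries of a pool, so chance differences between pools of mice are not excluded for any of these counts.

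For pairs of groups 10 groupings exist, too few for a share under 0.05. In males 1 of 10, the real grouping, reached the count in each comparison: 2223 for dnTGFB against WT (highest other 1214), 803 for WT secretin against WT (0), 3041 for dnTGFB secretin against dnTGFB (0) and 625 for dnTGFB secretin against WT (0). In females 10 of 10 groupings reached the real count of 0 in each comparison, as any grouping must, and the highest others were 0, 2, 0 and 34 in the same order.

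The heart muscle and Y-linked transcripts in 4 libraries labelled female leave RNA of male heart tissue in these libraries open. Their lowest heart muscle sum was 19.5 times the highest of the other 8 female libraries, which describes the pattern and does not test it, because the libraries were picked for it. A small carry-over of reads from male libraries is unlikely, since their median Ddx3y was 70.8% of the male median (58.7 against 83 CPM). Heart genes switched on in female cholangiocytes, the biological explanation tested, are also unlikely, since the lowest Ddx3y was 7.77 times the highest of the other female libraries, and female cells carry no Y chromosome. A mislabelled sample of another tissue also stays open. Xist stood at 12.68 and 29.67 CPM in female WT secretin libraries 2 and 3 and at 74.69 and 30.17 CPM in female dnTGFB libraries 1 and 2. Male libraries held at most 5.74 CPM outside WT secretin, which held 33.98 to 42.43 CPM. These levels argue against RNA of male tissue alone in the 4 libraries.

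The close agreement of female libraries under different group names leaves 1 RNA sequenced under 2 group names open. The less close of the 2 pairs, which were picked for their closeness, had a chi-square of 1.42 per gene, where male replicates reached 1.44 to the nearest and 1.56 to any replicate. Correctly named triplicates of pools that do not differ were the biological explanation tested. The 4 libraries were picked for a nearer library in another group, so a larger distance to their own groups was fixed in advance. Female libraries nearest to their own group lay at 3.1 to 4.22 per gene, so the 3.97 of dnTGFB secretin library 3 does not decide. For WT library 2, dnTGFB secretin library 1 and WT secretin library 1 the explanation is unlikely, at 10.55, 28.82 and 62.68. Which of the names would be right was not tested, and the sources used here do not settle it.

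Lower biliary and higher hepatocyte genes in male dnTGFB were weighed against 2 technical sources, the first without the 2 male libraries that stood apart and the second with all libraries. More hepatocyte RNA diluting all other cell types alike does not by itself give the T cell values. The T cell median exceeded the biliary median by 3.03 (1.81 against −1.22), where their spread allowed 1.08, while B cell markers stood at −3.20. T cell markers could rise on their own, so this gap cannot decide whether dilution lowered the biliary genes. Mitochondrially encoded counts taking depth from other genes are unlikely as the cause, since without them the highest dnTGFB biliary sum was 58.2% of the lowest in WT (3184 against 5467 CPM of nuclear counts). A change in the cells captured from a pool and a change within bile duct cells were not told apart, and 1 pool per group leaves both open.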

How the results depend on the processing

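Leaving out the libraries that stood apart and leaving out the mitochondrially encoded genes were alternatives chosen after the data were seen, the others before. Over all alternatives 459 counts of genes stayed within 1.5 times and 279 moved further. The 459 include counts where the main fit and the alternative both called no gene, as mostly in female comparisons of groups. Of the values of named genes 6387 kept their status, 1734 ended a call, 76 gained one and 10 reversed. The 6387 include genes called in neither fit, so they are not a count of calls kept. Of 96 camera calls of gene lists in males, 1 held with an estimated correlation, 43 with the rotation test fry and 93 with the replicate block, and the others ended. In males the biliary, B cell and acinar medians kept their direction under all scalings between dnTGFB and WT. Depth limits the female WT libraries and male dnTGFB library 3 for weakly expressed genes such as Sct, and the simulated data gave fewer recovered genes in females. Where a value below moved or reversed, the cause was not tested.

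DESeq2 called 1466 genes in male WT secretin against WT, 1442 in dnTGFB secretin against WT, 3924 in the male interaction, 742, 2418 and 431 in female dnTGFB against WT, WT secretin against WT and dnTGFB secretin against dnTGFB, 5834 in the female interaction, and 2238, 1680 and 2743 in the sex differences in the effect of genotype, of secretin in WT and of secretin in dnTGFB. It shared 132, 159 and 101 genes between the sexes for dnTGFB against WT, WT secretin against WT and dnTGFB secretin against dnTGFB. With limma-voom the counts were 1357 and 1091 in male WT secretin and dnTGFB secretin against WT, 0 in the female interaction, and 761, 247 and 479 in the sex differences.

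With library totals only, 4239 genes were called in male dnTGFB against WT, 6587 in dnTGFB secretin against dnTGFB, 3767 in the male and 0 in the female interaction, 740 in the sex difference in the effect of genotype and 1 in that of secretin in dnTGFB. With no low-count filter the sex differences in the effect of secretin had 8 genes in WT and 764 in dnTGFB. With the stricter filter, male dnTGFB against WT had 1267, dnTGFB secretin against dnTGFB 1907, and the sex differences 696, 7 and 745.

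The fit of only the 2 groups compared called 0 genes in male dnTGFB against WT, 1414 in WT secretin against WT, 500 in dnTGFB secretin against dnTGFB and 1697 in dnTGFB secretin against WT. Without the libraries that stood apart 3823, 2321 and 2209 genes were called in male dnTGFB, WT secretin and dnTGFB secretin against WT, 4889 in the male and 0 in the female interaction, and 329 and 700 in the sex differences in the effect of secretin in WT and in dnTGFB. Female WT secretin and female dnTGFB then hold 1 library each, assumed to vary like the other groups, which bears on the female interaction (both), the sex difference in WT (the first) and that in dnTGFB (the second). In that fit the reversed values were, for male dnTGFB against WT, Cdkn1a at 0.16 and Ddx3y at 0.39, for dnTGFB secretin against dnTGFB, Tgfbr2 at −0.14, and for the female interaction Myot at 1.00, Lrrc10 at 0.54, Mybphl at 2.62, Sdhb at 0.93, Ndufs1 at 0.47, Uqcrc1 at 0.70 and Cyc1 at 0.66.

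Leaving out each library in turn gave 1064 to 3152 genes in male dnTGFB against WT, 295 to 833 in WT secretin against WT, 868 to 3788 in dnTGFB secretin against dnTGFB, 286 to 574 in dnTGFB secretin against WT and 1073 to 3793 in the male interaction. In females it gave 0 to 4739 in WT secretin against WT, 0 in the other comparisons of groups and 0 to 7818 in the interaction. The sex differences ranged over 737 to 3177, 0 to 4184 and 1 to 2886.

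With the replicate number as a block, 1722, 554, 2160 and 469 genes were called in the 4 male comparisons, 1746 in the male interaction, 0 in all female comparisons and the female interaction, and 963, 0 and 610 in the sex differences. The numbers do not pair the libraries: deviations from the group means of libraries with the same number correlated with a median of 0 in males (over 0.1 in 2 of 18 pairs) and −0.14 in females (5 of 18).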

Other observations

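Sums of tissue markers and the comparisons of libraries in this part were chosen after the data had been seen. Across the male groups, trypsinogen and elastase genes of the exocrine pancreas were higher in both secretin groups than in untreated WT. Cela3b, an elastase gene, was 0.605 ± 0.373 CPM in WT, 2.74 ± 1.53 CPM in dnTGFB, 9.98 ± 0.858 CPM in WT secretin and 21.5 ± 1.65 CPM in dnTGFB secretin (n = 3 libraries of 1 pool each). In females the sum of acinar markers was 941.3, 1304.8 and 1047 CPM in WT, 190.5, 5.7 and 12.2 CPM in WT secretin, 28.7, 11.7 and 590.9 CPM in dnTGFB and 1273.6, 575.5 and 206.7 CPM in dnTGFB secretin, and edgeR called 0 of the 10 markers in each of the 4 comparisons between female groups. The sum was 180.8 to 182.2 CPM in male WT secretin, where Xist stood at 33.98 to 42.43 CPM, so the increase there is not separated from female RNA. It was 398.8 to 427.8 CPM in male dnTGFB secretin, where Xist stood at no more than 1.31 CPM, and 39.9 to 70.3 CPM in male WT. Whether pancreatic tissue entered the cell preparations was not tested.

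Female WT library 2 and female dnTGFB secretin library 1 carried placental transcripts at 1109 and 1119 CPM and transcripts of stratified squamous epithelium at 4765 and 4713 CPM. Sct, which otherwise stood at no more than 1.67 CPM, was 5.28 and 6.61 CPM in these libraries. Psg21, a placental gene, was 160.43 and 166.29 CPM there, and 15.06 CPM in male WT library 1 against 2.77 and 1.85 CPM in WT libraries 2 and 3.

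Male WT library 1 was nearest to male dnTGFB library 2, with a chi-square of 7.3 per gene against 40 to its own group. Male dnTGFB library 3 was nearest to female dnTGFB library 1, at 34.31 against 78.42 to its own group. Female dnTGFB library 3 was nearest to female WT library 1, at 4.85 against 47.46.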
